A study of Homo sapiens with 4 samples.

How the data were processed

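Total RNA from 4 HUES8-derived cultures at the early pancreatic progenitor stage, 2 wild type and 2 heterozygous for GATA6, was sequenced on an Illumina platform. Per the labels' protocols, the stem cells were kept on a feeder layer (iMEF) before differentiation, the medium of this stage held FGF10, SANT-1 (a Hedgehog pathway inhibitor), retinoic acid and LDN-193189 (a BMP receptor inhibitor), and RNA was taken in TRIzol and purified on a miRNeasy column. The deposited table gives 1 value per gene and library in the unit of scaled read counts (signal), which the authors obtained by counting reads per gene with HTSeq and scaling with DESeq on build hg19, per the submitters' processing notes. The aligner, the gene annotation, the tool versions, the strandedness of the libraries and filters on genes were not given in the sources used here. Gene names and identifiers are those of the table; 25 symbols appear in it as calendar dates, a spreadsheet conversion, and none of the genes named here is among them.

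The lowest value in the table was 1, and every value minus 1 was a whole number of reads times 1 factor per library, so 1 had been added to each scaled count. The factors were 0.971 and 1.03 for wild-type lines 1 and 5 and 1.01 and 1.06 for heterozygous lines 32 and 33. With a tolerance of 0.001 reads, 100% of the values came out whole in each library. The recovered totals were 31629814, 29620948, 30156736 and 29045542 reads over 23497 genes. Counting error alone is 31.6% of the value at 10 reads. Chi-square tests of the recovered reads gave 6.52 per degree of freedom for the wild-type pair and 7.81 for the heterozygous pair, so no 2 libraries agreed within counting noise, and none was counted as a duplicate. The table held 0 value columns of other samples, and 8 genes with 0 reads in all libraries.

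Samples were grouped by the genotype in the labels. The main test was limma 3.58.1 (R 4.3.3) with a trend of spread with expression, on log2 of the scaled count plus a pseudocount of 1, for genes with a mean scaled count of at least 10; this left 18519 genes. P-values are two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + pseudocount) scale, which understates changes of low genes. Because the deposited value already holds the added 1, its log2 was used as it stands; adding a further 1, the literal reading of the plan, was run as an alternative. The count tests of edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads as alternatives and called 448 and 757 genes, of which 438 and 436 were among the 454 limma calls. All 454 called genes had non-overlapping lines, as had 50.5% of tested genes, where chance gives 33.3%.

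Before the data were examined, 35 gene lists with 623 entries were fixed from textbook markers of the pancreas and other tissues, of the pathways the medium acts on and of RNA quality; 553 entries were in the table. For each list the members past the threshold were counted over all tested genes and adjusted over the list alone, and 32 lists with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01, with adjustment over the lists. Of these, 15 passed. With an estimated correlation 0 lists passed, and 0 had an unadjusted camera p under 0.05 (smallest 0.055). That setting takes its p-values on the residual degrees of freedom of the 4 libraries, the preset on those of all tested genes. A list could therefore hardly pass under it, whatever its estimate. The BMP and FGF lists lost their calls there too, with estimates of -0.0054 and -0.041, below the preset 0.01. A loss under that setting therefore does not show by itself that correlation among members made a call. Other called lists had estimates far above the preset: 0.49 for hepatic, 0.43 for immediate early, 0.40 for pluripotency and 0.38 for endothelial genes. They were 0.37 for glycolysis, 0.25 for cell cycle, 0.17 for neural and 0.053 for pancreatic progenitor genes. Where the estimate is high, the camera p-values at the preset may be much too small. The genes named were also set by a rule fixed then: GATA6; the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 50 and both heterozygous lines on the same side of both wild-type lines, leaving out XIST, Y-linked genes and genes without an official symbol; up to 4 members per list with the largest change among those past the threshold, or up to 3 of the highest mean where none passed; and 9 fixed genes, of which 8 were in the table. Some genes that the rule names are not reported here. Other genes, chosen after their values were seen, are the list members beyond these (TTR, TF, TBX3, TIE1, COL1A1 and COL1A2), the overlapping genes and those of the closing section.

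The alternatives were pseudocounts of 0.5, 2 and 8, no filter and a filter of 50, TMM and quantile scaling, edgeR, DESeq2, limma without the trend and with robust fitting, an estimated correlation for the lists, and leaving out each line in turn; the pseudocount of 2 was chosen after seeing the data. Data were simulated from the real means and library sizes to test the procedure for this comparison over 18557 genes. Limma recovered 47.0% of genes changed 1.5-fold, 74.6% at 2-fold and 98.4% at 4-fold, with 16 false calls (10.1% of calls). In the same simulation edgeR made 14 false calls and DESeq2 8. In a further draw camera called a list changed 1.5-fold and 0 of 30 unchanged lists. Genes were drawn independently there, so it does not show how often camera calls unchanged lists of correlated genes. GENCODE release 29, on GRCh38, was used only for exon overlaps, neighbour order, distance between neighbours, GC content and transcript length, since its build is not that of the table, and no coordinates are given. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and figures.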

Results

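RNA sequencing was performed on total RNA from HUES8 cells, a human embryonic stem cell line, differentiated to PP1, the early pancreatic progenitor stage. Of the 4 libraries, 2 came from wild-type lines (1 and 5) and 2 from lines heterozygous for a GATA6 mutation (32 and 33). GATA6 encodes a zinc finger transcription factor of endoderm and heart development. The comparison of the genotypes asks which transcripts depend on a full dose of GATA6 in early pancreatic progenitors. The libraries held 31629814 and 29620948 gene-assigned reads for wild-type lines 1 and 5 and 30156736 and 29045542 for heterozygous lines 32 and 33. A single library per line was analysed. The labels do not say whether the lines were differentiated separately, and the names of the value columns share a number whose meaning is not given. The limma p-values rest on the spread between these lines and on a spread pooled across genes (prior degrees of freedom 5.47). Camera p-values at the preset correlation and the permutation p-values given later compare genes with other genes. They do not measure the spread between lines.

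GATA6 and several regulators of pancreatic identity were lower in the heterozygotes, while no change was detected for GATA4, FOXA2 and SOX17. GATA6 had scaled read counts of 4967 and 5059 in the wild-type lines and of 3149 and 3497 in the heterozygous lines. Its mean fell from 5013 ± 64.9 to 3323 ± 246 (SD, n = 2 lines each), a log2 fold change of -0.59 ± 0.06 (SE; limma adjusted p = 0.00703). PDX1, the master regulator of the pancreatic bud, fell from 3338 ± 146 to 2236 ± 98.1 (log2 fold change -0.58 ± 0.06, limma adjusted p = 0.00695). SOX9, which maintains pancreatic progenitors, fell from 2083 ± 3.64 to 972 ± 109 (-1.10 ± 0.08, limma adjusted p = 0.00188). By contrast GATA4, the closest paralog of GATA6, stood at 11285 ± 305 and 11228 ± 655, with a log2 fold change of -0.01 (limma adjusted p = 0.96). Log2 fold changes were -0.10 for FOXA2 and -0.10 for SOX17, with limma adjusted p of 0.34 and 0.619.

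Of the 16 tested members of the pancreatic progenitor list, 5 fell, none rose and 11 did not pass the test. When adjusted over the list alone, 8 fell and none rose. Besides SOX9 and PDX1, the homeobox regulators PROX1 (log2 fold change -0.88), HHEX (-0.66) and MNX1 (-0.54) fell. The list as a whole was lower, with a median log2 fold change of -0.53 (camera adjusted p = 5.1e-06; adjusted p = 0.50 with an estimated correlation). The median was -0.35 without wild-type line 1 and -0.34 with a filter of 50. PROX1 did not pass without line 33 (limma adjusted p = 0.0701) or with robust fitting (0.0637), and MNX1 did not pass without wild-type line 1, line 32 or line 33 (0.113 to 0.135). GATA6 and PROX1 share 240 and 171 exon bases with their antisense genes, GATA6-AS1 and PROX1-AS1, which reached 13.3% and 13.7% of their levels. Reads in those stretches could not be told apart, because strand use in counting was not given in the sources used here. GATA6-AS1 itself had a log2 fold change of 0.03 (limma adjusted p = 0.898).

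**Figure D1:**
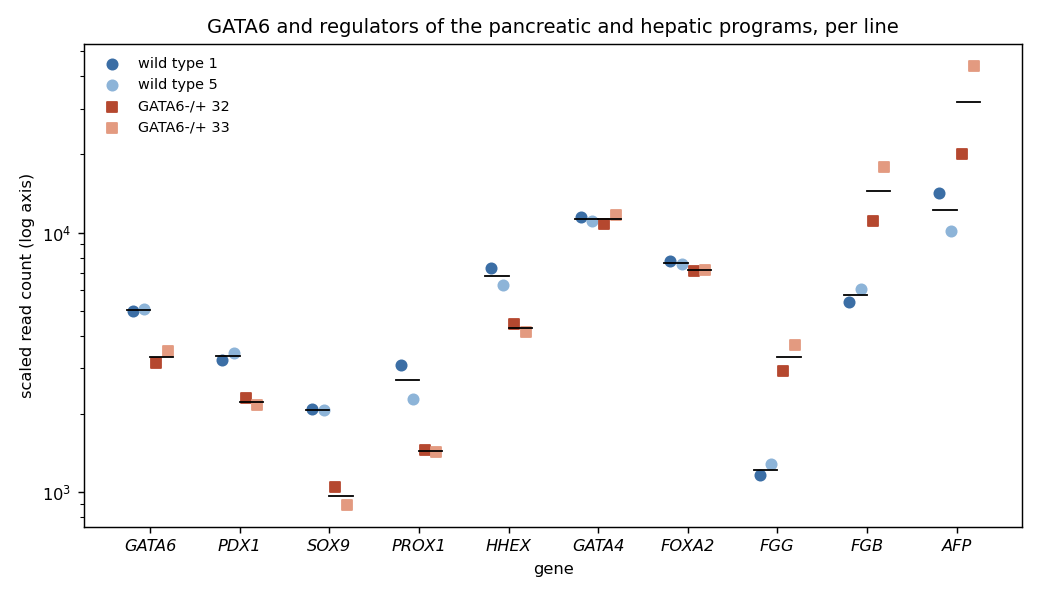
Scaled read counts (log axis) of GATA6 and of regulators and products of the pancreatic and hepatic programs in each line; circles are wild-type lines, squares are heterozygous lines and bars are the mean of 2 lines. GATA6 lies at 4967 and 5059 in the wild-type lines and at 3149 and 3497 in the heterozygous lines, while GATA4 overlaps between the genotypes.

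Across the transcriptome, 454 of 18519 tested genes differed between the genotypes (2.45%; limma, adjusted p under 0.05), with 166 genes higher and 288 lower in the heterozygotes. Among the largest rises with a mean count of at least 50, LUM, a collagen-binding proteoglycan, rose from 19.1 ± 2.23 to 255.3 ± 56.6 (log2 fold change 3.66 ± 0.23, limma adjusted p = 0.00135). COL3A1, the chain of type III collagen, rose from 512 ± 14.8 to 2043 ± 303 (1.99 ± 0.10, limma adjusted p = 0.000715). ESM1 (2.50), PLVAP (2.47), CD93 (2.20) and CD34 (1.63), all known from endothelial cells, were among the 12 largest of these rises, as were HAPLN1 (1.80), a hyaluronan link protein, and A2M (1.93), a protease inhibitor. SIX6 (2.40), a homeobox gene of the eye and pituitary, SMLR1 (1.84) and LINC00348 (1.55) also belonged to that set.

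Among the largest falls with a mean count of at least 50, GIF (current symbol CBLIF), gastric intrinsic factor, fell from 915 ± 41.2 to 219.8 ± 4.94 (log2 fold change -2.05 ± 0.09, limma adjusted p = 0.000475). TCN1, another vitamin B12 binding protein, fell from 357 ± 13.7 to 74.4 ± 14.8 (-2.26 ± 0.17, limma adjusted p = 0.00188). CPB1, a pancreatic carboxypeptidase, fell from 6272 ± 3565 to 1321 ± 206 (-2.13 ± 0.33, limma adjusted p = 0.0232), and its wild-type lines themselves differed, at 8792 and 3751. SLC26A3 (-2.45), an intestinal anion exchanger, APOBEC2 (-2.35), SPOCK1 (-2.09), MYPN (-2.09) and MYBPC1 (-1.97), 2 sarcomere genes, SGCD (-1.81), LYPD1 (-1.87), NETO1 (-1.74) and the neural factor POU3F2 (-2.15) made up the rest. A2M and LYPD1 share 561 and 1180 exon bases with antisense genes, A2M-AS1 and GPR39, whose levels were 50.1% and 26.6% of theirs. Reads in those stretches leave the values of A2M and LYPD1 uncertain. SIX6, SLC26A3 and MYPN did not pass without line 32 or without line 33, nor did SMLR1, LINC00348, CPB1, MYBPC1, LYPD1 and SGCD without line 33; the limma adjusted p then ranged from 0.0529 to 0.104. With robust fitting CPB1, SLC26A3, SPOCK1 and LYPD1 did not pass (limma adjusted p 0.105 to 0.277).

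**Figure D2:**
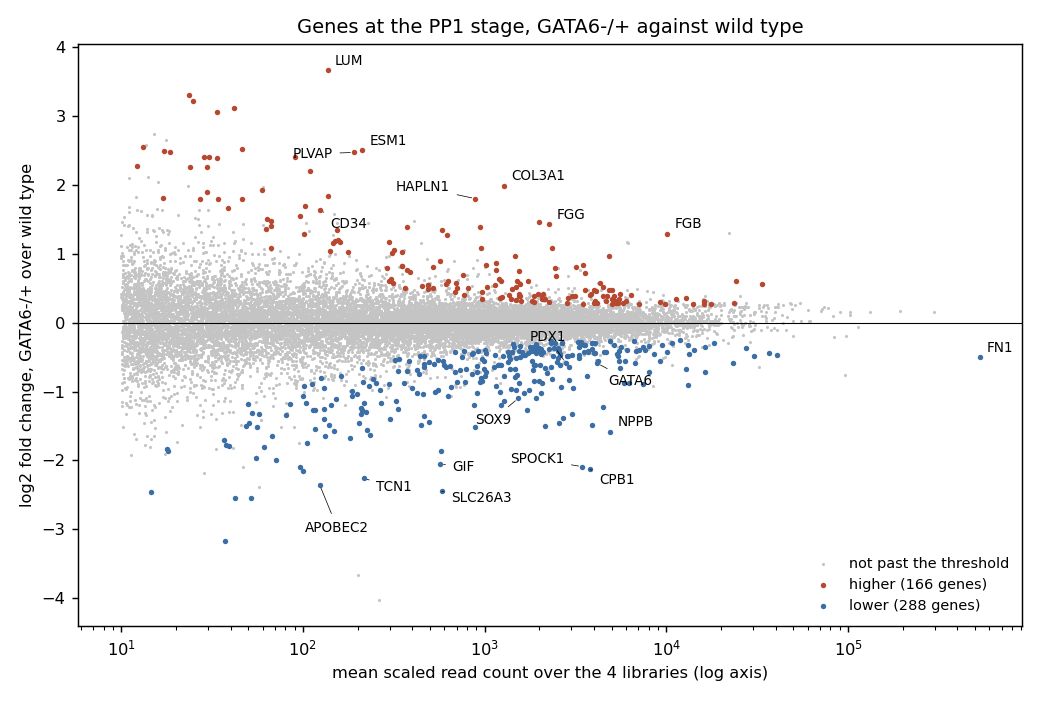
Log2 fold change of heterozygous over wild-type lines for the tested genes against the mean scaled read count of the 4 libraries (log axis); colours mark the 166 genes higher and 288 genes lower at a limma adjusted p under 0.05. XIST and Y-linked genes are not drawn. LUM lies highest among the coloured genes at 3.66, and FN1 has the highest mean count.

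The number of calls depended on single lines and on the model of the spread. Without line 33, 40 genes were higher and 108 lower, and without wild-type line 5 there were 535 higher and 645 lower. With a limma fit that ignored the trend of spread with expression, 0 genes passed (2680 at an unadjusted p under 0.05), while edgeR called 448 and DESeq2 757 on the recovered reads.

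Several hepatic transcripts were higher in the heterozygotes. The hepatic list had a median log2 fold change of 0.56 (camera adjusted p = 5.2e-06; adjusted p = 0.50 with an estimated correlation). Of 19 tested hepatic genes, 7 rose, 1 fell and 11 did not pass. Adjusted over the list alone, 11 rose and 2 fell. The fibrinogen chains FGG (log2 fold change 1.43), FGB (1.29) and FGA (0.79), the retinol carrier RBP4 (1.17), the secreted carriers TTR (0.56) and TF (0.60) and the transcription factor TBX3 (0.61) rose, and HHEX, shared with the pancreatic list, fell. FGG increased from 1224 ± 81.3 to 3315 ± 536 (limma adjusted p = 0.00188). AFP, alpha-fetoprotein, had scaled counts of 14250 and 10169 in the wild-type lines and of 20029 and 43805 in lines 32 and 33, and did not pass (1.30 ± 0.32, limma adjusted p = 0.0845). RBP4 did not pass without line 33 (limma adjusted p = 0.0939), FGB not with robust fitting (0.189), and AFP passed without wild-type line 1, wild-type line 5 or line 32 (0.00282 to 0.0434).

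Some endothelial genes were higher. The endothelial and blood list had a median log2 fold change of 0.95 (camera adjusted p = 5.5e-07; adjusted p = 0.50 with an estimated correlation). That median was 0.60 with a filter of 50, which drops scarce members, and 0.65 without line 32. Of the 16 tested members, 5 rose, none fell and 11 did not pass, or 9 rose and none fell adjusted over the list alone. ROBO4 (log2 fold change 2.49), SOX18 (2.47), CD34 (1.63), KDR (1.27) and TIE1 (1.09) rose; KDR, the main VEGF receptor, went from 366 ± 65.8 to 876 ± 33.1 (limma adjusted p = 0.00627). ROBO4 and SOX18 are scarce transcripts, at 33.5 and 26.5 scaled counts and at 36.5 and 27.6 in lines 32 and 33. With a pseudocount of 8 their log2 fold changes were smaller, at 1.60 and 1.62. In the mesenchyme list 3 of 20 members rose, LUM, COL3A1 and DCN (3.05), and FN1, fibronectin, fell (-0.50), with 4 higher and 3 lower adjusted over the list alone. The type I collagen genes had log2 fold changes of 0.02 for COL1A1 (limma adjusted p = 0.953) and 0.11 for COL1A2 (0.744), and the list median was 0.09 (-0.02 to 0.19 with 1 line left out; camera adjusted p = 0.081). The mesenchyme list passed with edgeR (camera adjusted p = 0.000303), DESeq2 (0.000498) and quantile normalization (0.0413), but not with an estimated correlation (0.67). Its median was 0.19 without wild-type line 5 and 0.13 without line 33. FN1 took 2.00% and 2.04% of wild-type reads against 1.48% and 1.38% in lines 32 and 33, and it did not pass when any 1 of the 4 lines was left out (limma adjusted p 0.0764 to 0.26). ROBO4 and SOX18 did not pass without line 32 or line 33 (0.0627 to 0.0729).

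Pluripotency genes were slightly higher in the heterozygotes, with a median log2 fold change of 0.49 over 20 genes (camera adjusted p = 5.2e-06; adjusted p = 0.50 with an estimated correlation). Of these 20, POLR3G (0.55) and ZFP42 (0.52) rose and 18 did not pass; adjusted over the list alone, 10 rose and 1 fell. POU5F1, the core pluripotency factor, was at 1258 ± 344 and 1846 ± 81.2 (0.58, limma adjusted p = 0.107). The wild-type lines differed from each other here: the list median was 0.62 above wild-type line 1 and 0.21 above wild-type line 5. ZFP42 did not pass without wild-type line 1, line 32 or line 33 and POLR3G not without line 32 or line 33 (limma adjusted p 0.0503 to 0.141), while POU5F1 passed without wild-type line 5 (8.56e-05). POLR3G shares 260 exon bases with MBLAC2 on the opposite strand, which reached 66.0% of its level. POU5F1 shares 248 with TCF19 likewise (22.4%). Reads in those stretches leave both values uncertain.

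**Figure D3:**
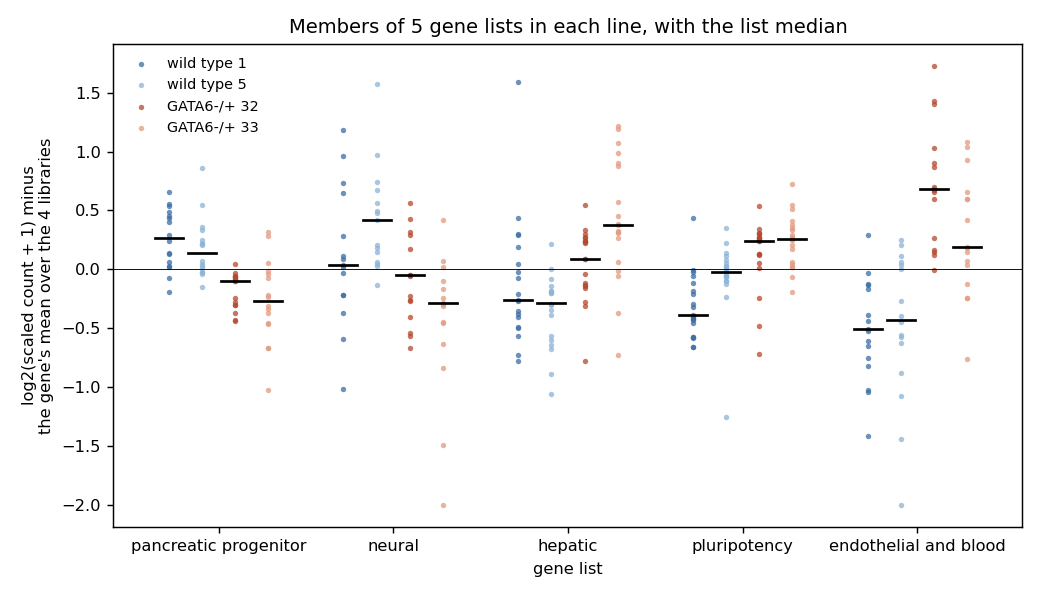
Log2(scaled count + 1) of each tested member of 5 gene lists, minus the gene's mean over the 4 libraries, in each line; points are genes and bars are list medians. Endothelial medians are 0.68 and 0.19 in lines 32 and 33 against -0.51 and -0.43 in wild-type lines 1 and 5, and pluripotency medians are -0.39 in wild-type line 1 and -0.02 in wild-type line 5.

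Some neural genes were lower. The neural median was -0.22 (camera adjusted p = 0.0018; adjusted p = 0.50 with an estimated correlation), -0.60 without wild-type line 1 and -0.35 without line 32. In the neural list, SOX1 (log2 fold change -2.54), POU3F2 (-2.15), PAX6 (-1.40) and NCAM1 (-0.86) fell, none of 15 members rose, and 5 fell adjusted over the list alone. In the endocrine list PAX6 and INSM1, a driver of endocrine differentiation (-0.74 ± 0.07, limma adjusted p = 0.00627), fell and 10 of 12 members did not pass; 3 rose and 3 fell adjusted over the list alone. Its median was 0.09, its mean -0.07 and its test pointed down (camera adjusted p = 0.48); the median was -0.41 without wild-type line 5, 0.19 without wild-type line 1 and -0.45 with a filter of 50, so its direction is unknown. PAX6 overlaps ELP4 on the opposite strand, whose level was higher than its own (726 against 71.4 scaled counts in the heterozygotes), so its value is uncertain. SOX1 and NCAM1 did not pass without line 33 (limma adjusted p = 0.0889 and 0.0978), nor SOX1 with robust fitting (0.058).

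A few members of 3 stress-response lists fell. In the p53 response list GDF15 (log2 fold change -0.62), CDKN1A (-0.49) and TP53INP1 (-0.47) fell, 13 of 16 members did not pass, and 7 fell adjusted over the list alone. The p53 median was -0.19 (camera adjusted p = 8.3e-06; adjusted p = 0.50 with an estimated correlation). In the unfolded protein and integrated stress list CHAC1 (-1.07), ATF3 (-0.79) and ASNS (-0.64), targets of ATF4, fell and 14 of 17 did not pass, with 4 lower adjusted over the list alone and a median of -0.08 (camera adjusted p = 0.01; adjusted p = 0.50 with an estimated correlation). ATF3, DUSP1 (-0.67) and JUN (-0.36) fell in the immediate early list of 16, 4 fell adjusted over the list alone, and its median was -0.14 (camera adjusted p = 0.014; adjusted p = 0.67 with an estimated correlation). Its median was -0.07 without line 33, -0.23 without wild-type line 1 and -0.22 with a filter of 50, and that of the stress list was -0.14 without line 33. The stress list was not called without line 32 (camera adjusted p = 0.137), nor the immediate early list without wild-type line 5 (0.101) or line 33 (0.0915). Without line 33, GDF15, CDKN1A, TP53INP1, CHAC1 and JUN did not pass (limma adjusted p 0.0561 to 0.163); CDKN1A did not pass when any other line was left out either (0.0632 to 0.0707), nor JUN without wild-type line 1 (0.0595). ATF3 did not pass with robust fitting (0.0735).

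A few members of the signalling lists changed. In the BMP list SMAD9 (log2 fold change 0.80) and ID2 (0.41) rose, and 8 rose and 1 fell adjusted over the list alone; the median was 0.26 (camera adjusted p = 0.017; adjusted p = 0.50 with an estimated correlation). In the FGF list the feedback inhibitor SPRY2 rose (0.35) and DUSP6, another one, fell (-0.49), and 6 rose and 2 fell adjusted over the list alone; the median was 0.20 (camera adjusted p = 0.028; adjusted p = 0.50 with an estimated correlation). The FGF list was not called by edgeR (0.0562), without the trend (0.0534) or without wild-type line 1 (0.082). In the Notch list JAG1, a Notch ligand, fell from 1707 ± 31.2 to 746 ± 75.2 (-1.20 ± 0.08, limma adjusted p = 0.00168), as did DLL1 (-0.38) and NOTCH2 (-0.34); 1 rose and 3 fell adjusted over the list alone, and the median was -0.05 (-0.09 to 0.06 with 1 line left out; camera adjusted p = 0.26). The Notch list was called by edgeR (camera adjusted p = 0.0333) and by DESeq2 (0.00901), but not with an estimated correlation (0.67). Its median was -0.07 without wild-type line 1. IHH rose (1.09) in the Hedgehog list, where 1 rose and none fell adjusted over the list alone. The median of that list was 0.08, or -0.03 to 0.14 with 1 line left out (camera adjusted p = 0.27, or 0.67 with an estimated correlation). WNT11 rose (1.04) and FZD5 fell (-0.44) in the WNT list (1 rose and 2 fell adjusted over the list alone; median 0.08, or 0.02 to 0.13 with 1 line left out, camera adjusted p = 0.56). RBP4 rose and MEIS1 (-0.47) fell in the retinoic acid response list (2 rose and 5 fell adjusted over the list alone; median -0.10, or -0.17 to -0.09 with 1 line left out, camera adjusted p = 0.22). Without line 33, RBP4, SMAD9, ID2, SPRY2, DLL1, NOTCH2, WNT11, FZD5 and MEIS1 did not pass (limma adjusted p 0.0703 to 0.178). The same was true of ID2, SPRY2 and NOTCH2 without wild-type line 1, of SPRY2 without wild-type line 5 and of SMAD9 and SPRY2 without line 32 (0.0601 to 0.104). IHH did not pass with robust fitting (0.193).

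Small shifts were found in 5 further lists. The cell cycle list had a median of 0.08, or 0.14 without line 32, with no member past the threshold (22 tested; camera adjusted p = 0.00065; adjusted p = 0.50 with an estimated correlation), and TOP2A and MKI67 stood at 0.05 and -0.02. Mitochondrial transcripts had a median of 0.15 (15 tested; camera adjusted p = 0.00075; adjusted p = 0.50 with an estimated correlation) and took 3.44% and 3.34% of reads in the wild-type lines against 3.71% and 3.75% in lines 32 and 33. The gut tube epithelium list had a median of -0.07 (camera adjusted p = 0.015; adjusted p = 0.50 with an estimated correlation), and CDH1, E-cadherin, fell (-0.29) as its 1 call in 21. The epithelial extracellular matrix and adhesion list had a median of -0.12 with no member called (18 tested; camera adjusted p = 0.015; adjusted p = 0.50 with an estimated correlation). Adjusted over the list alone, 1 mitochondrial gene rose, 1 gut tube and 4 matrix genes fell, and no cell cycle gene passed. SLC2A3, a glucose transporter, rose (0.60) in the glycolysis and hypoxia list (17 tested, 2 higher and 1 lower adjusted over the list alone; median 0.19, camera adjusted p = 0.029; adjusted p = 0.67 with an estimated correlation). Its median was 0.07 without wild-type line 1, 0.09 without line 32 and 0.36 without wild-type line 5. That list was not called without wild-type line 1 (0.604), line 32 (0.56) or the trend (0.0714), nor after quantile normalization (0.0533). Nor were the gut tube list without line 32 (0.303), the mitochondrial list without wild-type line 5 (0.0637) and the matrix list without wild-type line 5 (0.121) or line 32 (0.306). CDH1 did not pass without wild-type line 1 (limma adjusted p = 0.078) or line 33 (0.122), nor SLC2A3 without line 33 (0.0707).

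The remaining lists were not called by camera in the main fit. CLDN18, a stomach claudin, fell from 3877 ± 857 to 1494 ± 431 (log2 fold change -1.39 ± 0.20, limma adjusted p = 0.0187), the 1 gene lower adjusted over the list alone, and NPPB, a natriuretic peptide of the cardiac list, from 7343 ± 1142 to 2463 ± 516 (-1.58 ± 0.15, limma adjusted p = 0.00496); with robust fitting neither passed (0.185 and 0.063). KIT rose (0.36) and LHX1 (-0.89) and HHEX fell in the definitive endoderm list, where 2 rose and 3 fell adjusted over the list alone. Its median was -0.10, or -0.10 to -0.05 with 1 line left out (camera adjusted p = 0.48). ETS1 rose (0.55) in the neural crest list, where 1 rose and none fell adjusted over the list alone. The neural crest median was 0.15, or 0.02 to 0.37 with 1 line left out (camera adjusted p = 0.20, or 0.5 with an estimated correlation). CDX2, an intestinal regulator, was at 2187 ± 214 and 3556 ± 1106 (0.67, limma adjusted p = 0.105). It passed without wild-type line 5 or line 32 (0.018 and 0.0031), while its log2 fold change was 0.35 without line 33. Median log2 fold changes were 0.36 for the GATA family, -0.06 for intestine, 0.01 for anterior foregut and lung, -0.13 for primitive streak and mesoderm and 0.14 for cardiac genes, with camera adjusted p of 0.37, 0.69, 0.60, 0.91 and 0.91. They were 0.16 for trophoblast, 0.07 for HOX 1 to 5, -0.01 for monogenic diabetes and -0.02 for cholesterol synthesis genes, with camera adjusted p of 0.58, 0.56, 0.65 and 0.65. With 1 line left out the medians ranged from 0.26 to 0.45 for the GATA family, -0.25 to 0.03 for intestine, -0.19 to 0.18 for anterior foregut and lung, -0.26 to 0.10 for mesoderm and -0.01 to 0.26 for cardiac genes. These ranges were 0.07 to 0.30 for trophoblast, -0.04 to 0.23 for HOX, -0.07 to 0.07 for diabetes and -0.07 to 0.06 for cholesterol genes, so the direction of most of these lists is unknown. The filter of 50 gave -0.13 for cardiac and 0.48 for trophoblast genes, and no filter gave 0.19 for mesoderm genes. Medians of the cardiac and of the anterior foregut and lung lists were positive while their means, -0.04 and -0.03, and their tests pointed down. Adjusted over the list alone, 3 GATA genes rose and 1 fell, 2 intestinal genes rose and 2 fell, 1 rose and 1 fell in both the mesoderm and the trophoblast list, 1 foregut and 1 cardiac gene fell, 2 diabetes genes fell, and no HOX or cholesterol gene passed. The stomach list, with 3 tested members, the non-polyadenylated histone list with 2 and the HOX 6 to 13 list with 0 were too small for camera. KIT, LHX1 and ETS1 did not pass without line 33 (limma adjusted p 0.0754 to 0.172), nor LHX1 and ETS1 without wild-type line 1 or line 32 (0.0528 to 0.168).

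The libraries grouped by genotype. Pearson correlations of log2 values across genes were 0.993 between the wild-type lines, 0.993 between the heterozygous lines and 0.987 to 0.992 between genotypes. The first principal component, with 54.7% of the variance, placed wild-type lines 1 and 5 at -30.2 and -15.4 and lines 32 and 33 at 18.3 and 27.4. The second, with 26.9%, separated the lines within each genotype. Between genotype means 42 genes differed over 4-fold, against 16 between the wild-type lines and 23 between the heterozygous lines. With a minimum mean count of 50 these numbers were 17, 3 and 5. They set means of 2 lines against single lines, which vary more. Between single lines of unlike genotype, 49 (wild-type line 5 and line 32) to 98 genes (wild-type line 1 and line 33) differed over 4-fold without that minimum.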

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

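All alternatives but the pseudocount of 2 were fixed before the data were examined. Of 1524 comparisons of a named gene with its value under an alternative, 1338 kept their side of the threshold, 171 were no longer past it, 14 passed newly and 1, FN1, was left with no change. FN1 went from -0.50 to 0.00 (limma adjusted p = 1) under quantile normalization, which gives the top gene of each library 1 common value by construction. Limma without the trend called 0 genes and so ended all 70 of these named calls, the most of any alternative. It also ended that of GATA6, which these comparisons leave out. Many of the other losses came from leaving out single lines. Robust fitting ended 11, quantile normalization 7 with FN1, the filter of 50 7, no filter 4, DESeq2 3, and edgeR, TMM and pseudocounts of 2 and 8 each 1. MNX1 was lost with edgeR, DESeq2, the filter of 50 and quantile normalization (0.0524 to 0.0631). For the lists, 471 of 510 comparisons kept their side of the threshold, 29 lost and 10 gained the call. Of these 1338 and 471 together, 35 changed sign while past the threshold in neither fit. Genes higher in the heterozygotes numbered 166 in the main analysis, 100 with a filter of 50, 331 with DESeq2 and 0 in limma without the trend. Genes lower numbered 288, and 0 without the trend. With the filter of 50, 424 of the 454 main calls were still tested and 323 passed. For both 0 counts, 2680 genes had an unadjusted p under 0.05 in that fit, and edgeR called 448. The change of GATA6 stayed at -0.59 without the trend but with a limma adjusted p of 0.234; the causes of the losses without the trend and with that filter and of the gain with DESeq2 were not tested. With an estimated correlation 0 lists were called, against 15, and the losses included lists whose estimate lay below the preset. A list could hardly pass there, since those p-values rest on the residual degrees of freedom of the 4 libraries. With a filter of 50, 17 genes differed over 4-fold between genotype means, against 42, since fewer genes were counted. Leaving out 1 line gave 40 to 535 higher and 108 to 645 lower genes; the lone line left in a genotype is then assumed to vary like the other group. The lowest numbers came without line 33 (136 of its 148 calls shared with the main 454) and the highest without wild-type line 5 (429 shared of 1180). No paired analysis was possible because the line numbers of the genotypes differ. At 10 reads, counting error is 31.6% of a value, so changes of low genes are the least certain.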

Other observations

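All tests in this part were chosen after the results were seen. Genes outside the naming rule, picked after their values were seen, are given here as values. RFX4 and DBX1, transcription factors of the developing nervous system, fell from 68.2 ± 16.2 to 6.71 ± 1.99 scaled counts (log2 fold change -3.17 ± 0.34, limma adjusted p = 0.00726) and by 2.46 on the log2 scale (0.0471). STAT4 fell from 354 ± 18.8 to 113.5 ± 0.159 (-1.63 ± 0.13, limma adjusted p = 0.00193), and JAK1 (-0.43) and IL6R (-0.54), also of cytokine signalling, fell. So did the receptors NPY1R (-1.32) and NPY5R (-0.98) and the smooth muscle genes MYOCD (-1.65), MYL9 (-0.62) and ACTG2 (-0.86). C7 (3.31), ITGA8 (3.12), FLI1 (2.39), LMO2 (1.79), CD248 (1.66) and FLT1 (1.06) rose. HESX1, a homeobox gene of the forebrain and pituitary, rose by 1.39 on the log2 scale (limma adjusted p = 0.025).

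CHCHD2, a mitochondrial protein gene, and SLITRK4 differed between lines of 1 genotype. CHCHD2 had 790 scaled counts in wild-type line 1 and 4.12, 2.03 and 7.42 in wild-type line 5 and lines 32 and 33. SLITRK4 had 383, 386 and 274 in wild-type lines 1 and 5 and line 32, and 1.06 in line 33. Neither passed between genotypes (limma adjusted p = 0.37 and 0.299). Ribosomal protein genes took 3.85% and 4.07% of reads in wild-type lines 1 and 5 and 4.82% and 4.49% in lines 32 and 33. YBX3 (-0.89) and its pseudogene YBX3P1 (-0.81), and EEF1B2 (0.28) and its pseudogene EEF1B2P3 (0.29), passed together, and reads shared between such copies leave these values uncertain.

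The endothelial list (adjusted p = 0.50 with an estimated correlation) and COL3A1, LUM and DCN were higher in the heterozygotes. The mesenchyme list as a whole was not called in the main fit (camera adjusted p = 0.081) or with an estimated correlation (0.67). It was called with edgeR (camera adjusted p = 0.000303), DESeq2 (0.000498) and quantile normalization (0.0413). A trend with GC content or transcript length is argued against as the whole cause: after correction of each library for both, the endothelial list had a median of 0.96, against 0.95 before, while calls among the 18058 genes with both values went from 431 to 354. Whether more endothelial cells in the heterozygote cultures account for the list cannot be told here. Of its 16 members, 11 were higher in both heterozygous lines and 0 lower in both. This lay between the bounds set for the explanation (12 or more) and against it (8 or fewer). The list was picked for its rise in these same libraries, so the count is no separate test. A bulk library does not separate more cells from more transcripts per cell. Fibroblasts could bring COL3A1, LUM and DCN, and would bring type I collagen too; the summed gain of COL1A1 and COL1A2 was 0.21 of the gain of COL3A1, but it ranged from -1.51 to 1.49 over the 4 pairs of lines, so this stays open. An effect of GATA6 dose within cells also stays open, untested.

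Hepatic genes were higher and pancreatic progenitor genes lower by camera with the preset correlation (adjusted p = 0.50 for both with an estimated correlation). A single line does not account for it: with each line left out both lists kept their direction, with camera adjusted p of at most 0.000362, though the preset correlation underlies these values. A uniform dilution by a lower share of pancreatic progenitors would raise alike those markers of other cell types that progenitors lack. The 11 lists of other cell types moved apart (Kruskal-Wallis statistic 37.0, permutation p = 0.0001 over 9999 permutations of 134 genes, which are not independent replicates). Their medians went from -0.22 for neural to 0.95 for endothelial genes, with pluripotency at 0.49. Which members progenitors express is not known here, and some were abundant, such as LIN28A (mean scaled count 39812) and NES (6988). The list changes had also been seen before this test was chosen, so it does not decide on dilution. The hepatic median exceeded the neural one by 0.78 (permutation p = 0.00064). The hepatic list was picked for its rise and the neural list for its fall, so this difference is no separate support. With a line left out the neural median ranged from -0.60 to -0.18 and the hepatic from 0.52 to 0.63. The GC and length correction left medians of 0.57 for the hepatic and -0.53 for the pancreatic list. An effect of GATA6 dose within cells and a larger share of hepatic or of several other cells stay open, untested. Dilution by a lower share of pancreatic progenitors stays open too.

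Neighbouring genes changed together. Among 14506 tested protein-coding genes in chromosome order, 21 adjacent pairs were called in the same direction, against a mean of 6.57 when calls were permuted among genes of like expression (permutation p = 0.0001, the smallest that 9999 permutations can give), which argues against chance placement; pairs called in opposite directions numbered 8 against 5.62 (permutation p = 0.21). The pairs in the same direction include GIF and TCN1, LUM and DCN, NPY1R and NPY5R, FGB, FGA and FGG, KIT and KDR, and ETS1 and FLI1. Of the pairs, 5 share the first 3 letters of their symbols. This count misses related genes with unlike symbols, such as the fibrinogen chains and the vitamin B12 binding proteins GIF and TCN1. Reads running into an adjoining gene are argued against for the pairs at least 10 kb apart, 11 against 3.74 (permutation p = 0.0012), but remain possible for closer ones such as CBLL1 and SLC26A3, and a gained or lost large segment by the 0.09 that was the largest absolute median over windows of 60 expressed neighbours. Regulation shared by neighbouring or related genes may contribute and was not tested. In simulation, 5 of 100 random placements and 20 of 20 sets with 15 planted pairs gave a permutation p under 0.05. The random placements came from the same shuffling as the permutations, so the simulation checks the procedure alone.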
